A study of Arabidopsis thaliana with 24 samples.

How the data were processed

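The data are 24 single-colour Agilent arrays of Arabidopsis thaliana roots in 10 groups, given by N form (ammonium or nitrate), time after transfer (0, 15 or 180 min) and N supply after transfer. The labels call the 3 replicates per time point independent replications, and each is a pool of 6 plants. The p-values below measure the spread between these samples. In the main fit this spread includes differences between replicate numbers and scan batches. Per the labels' protocols, RNA came from about 100 mg of root, and 50 ng of it was transcribed with an oligo-dT primer and labelled with Cy3.

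Per the file headers, the scanner files hold Agilent Feature Extraction output. The deposited processed signal is an intensity from which background had been subtracted within the array, with surrogates in place of low signals and no scaling between arrays. The files also hold the raw spot intensity and local background, and flags for each spot, among them whether it lay well above background. The authors' value table holds log2 values that share nearly the same distribution across arrays (medians 8.14 to 8.15), as after quantile normalization, per the submitters' processing notes made with limma, whose steps and version are not stated. Each column of that table correlated best with the scanner file of its own sample (Spearman's rho 0.998 to 1.00, against at most 0.989 with another), so no array was found to be a copy of another.

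The main values were log2 processed signal minus the 75th percentile of the array's non-control probes. Probes were kept if well above background on at least 3 of the 24 arrays, which left 49391 of 59017. Spots of a probe were averaged, and for each gene the probe with the highest mean was tested, which gave 26725 genes or probe groups, 26297 with 1 locus and 428 with several that share probes and are not told apart. Gene names came from the array design and the gene table supplied. Of 29983 loci with their own probe, 29422 were in that table. Coordinates are the spans of the array design on TAIR10. Where no array of the lower group had the probe well above background, the change is given as a lower bound (at least) for the main values. Where only some arrays of that group did, the fitted change is given with their number, and its size is uncertain. The lower bounds carry no standard error and hold for the main processing only. They do not bound the true change, since another background correction (normexp) gave smaller changes for some of these genes.

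A group-means model over all 24 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, residual degrees of freedom 14, prior 2.96), with data.table version 1.17.8, and files were read and drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. P-values were adjusted over the genes tested with the Benjamini-Hochberg method, and a gene is called at an adjusted p under 0.05. There were 13 comparisons: nitrate-fed against ammonium-fed at 0 min, each later time against 0 min, the differences between both responses, roots without N against N-supplied controls, and the 15 min controls against 0 min. The samples, the main design, the alternative processing to be tried, the gene lists and the rule for naming genes were fixed before the data were examined. Arrays were also simulated for 26066 genes, with independent normal noise of each gene's residual spread over all groups. Known changes were added to the nitrate-fed 180 min group. There the fit recovered 22% of 50 genes changed 1.5-fold, 52% of 50 changed 2-fold, 78% of 50 changed 4-fold and 84% of 50 changed 8-fold, with 4.84% of its calls false. The simulated arrays lacked the correlation between real arrays of the same replicate number or scan batch, so these shares need not hold for the real data.

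Gene lists were written from general knowledge of the root: nitrate response, nitrate transporters and channels, nitrogen starvation and scavenging, ammonium assimilation, rapid touch and stress response, jasmonate, iron deficiency, phosphate starvation, sulfate starvation, potassium transport, circadian clock, energy and sugar starvation, cytokinin response, abscisic acid and dehydration, anthocyanin and flavonoid, low oxygen, and 5 marker lists (shoot photosynthesis, root hair, endodermis, vascular, dividing cells). Some genes stand in more than 1 list. Each was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 21 lists of a comparison, and its members were also adjusted over the list alone. Of 273 list results 112 passed with the preset correlation and 17 of these with an estimated correlation. The median, mean and test of a list differed in sign in 48 results, 0 of them among those that passed.

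The genes named were, for each comparison, those with the largest rises and falls among called genes with a symbol whose groups did not overlap on any array (from up to 12 per direction), up to 4 called members of each list, 12 N transport and assimilation genes in every comparison, and the gene with the smallest p. No check of overlap was made for the differences between responses or for groups with fewer than 3 arrays. Overlaps of calls were set against the number independent lists would share.

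The labels give replicate numbers 1 to 3. Among the 18 arrays without the N-supplied controls, deviations from the group means of arrays with the same number correlated over 0.1 in all 45 pairs (0.286 to 0.754, median 0.456), so the numbers were taken to pair the samples in the 7 comparisons among them. With the controls included the lowest such correlation was 0.0584 (70 of 71 pairs over 0.1). Comparisons with the controls share only 1 or 2 numbers and were not treated as paired. This scope was settled when the counts with the replicate block were already known. Replicates 1 and 2 were scanned in scan batch 1 and replicate 3 in scan batch 2, with another extraction protocol per the file headers, so pairing by number holds the scan batch as well. Arrays of replicates 1 and 2 of different groups correlated at -0.236 to 0.177 (median 0.0143), and within scan batch 1 arrays with the same number at 0.204 to 0.478 (15 pairs). The first principal component held 34.3% of the variance and separated replicate 3. The fit with the replicate number as a block had 12 residual degrees of freedom. The main fit left the pairing out, so its p-values can be too large in the 7 comparisons. At 15 min without N against 0 min it gave 944 (ammonium-fed) and 729 (nitrate-fed) genes at an unadjusted p under 0.05. With the block these counts were 2384 and 1590. Chance alone gives 1336 over the 26725 genes tested. Scan batch 2 holds 1 array per group and allows no test of its own.

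The alternatives were normexp background correction (offset 50) with the 75th percentile or with quantile normalization, the authors' value table, no filter on dim probes, the mean of all probes of a gene, the replicate number or the slide as a block, only the arrays compared, and leaving out each array in turn. The scan batch as a block and scan batch 1 alone were added after the data were seen. No sample was left out of the main analysis.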

Results

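Gene expression was measured in roots of Arabidopsis thaliana Col-0 on 24 single-colour Agilent arrays, each carrying Cy3-labelled cRNA from the pooled roots of 6 plants. The plants were 35 days old and had spent their last 5 days with either ammonium (1.5 mM (NH4)2SO4) or nitrate (3 mM KNO3) as the only N source. Roots were harvested without transfer (0 min) or 15 and 180 min after transfer to solution without N, with 3 arrays for each feeding regime and time, 18 in all. A further 6 arrays held roots moved to fresh solution that still contained the same N form, here called N-supplied controls. Each feeding regime had 2 such arrays at 15 min and 1 at 180 min. Between 70.6% and 80.9% of the non-control features of an array lay well above background, and no feature was saturated (0 on every array). Within groups the arrays correlated at 0.963 to 0.983 (Pearson's r across genes, which are not independent replicates). The number of arrays limits the precision of every value below. Log2 fold changes are given with their standard error from limma, and all p-values are adjusted with the Benjamini-Hochberg method. They rest on n = 3 arrays per group unless stated otherwise.

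The comparison of both feeding regimes at 0 min asked how roots adapted to nitrate differed from roots adapted to ammonium. The nitrate salt also held potassium and the ammonium salt sulfate. Unless other salts balanced these ions, their supply is mixed with N form in every comparison of both regimes. Effects on potassium and sulfate genes were not separated from those of N form. Nitrate assimilation genes were higher in nitrate-fed roots. NIA1 (AT1G77760), a nitrate reductase gene, was 90.8-fold higher (log2 6.50 ± 0.23, adjusted p = 3.71e-11). NIA2 (AT1G37130), the other nitrate reductase gene, was higher by 2.22 ± 0.21, NIR1 (AT2G15620), which encodes nitrite reductase, by 3.59 ± 0.34, and the nitrate transporter and sensor gene NRT1.1 (AT1G12110) by 1.96 ± 0.29. In the opposite direction, NRT2.5 (AT1G12940), a high-affinity nitrate transporter gene of N-starved plants, was lower. It lay well above background on only 1 of 3 nitrate-fed arrays, so the size of its difference is uncertain (-6.58 ± 0.46, adjusted p = 5.19e-07, and -4.21 with normexp and the 75th percentile). On TAIR10 the array design places NIA1 on chromosome 1 (29236005 to 29239367), NIR1 on chromosome 2 (6810552 to 6812666) and NRT2.5 on chromosome 1 (4416405 to 4418337).

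Of the 31 genes of the nitrate response list, 24 were higher in nitrate-fed roots and 0 lower (29 and 0 adjusted over the list alone). The median was 1.82, with an adjusted camera p of 5.8e-53, and 0.00116 with an estimated correlation. They included the transcription factor genes HRS1 (4.12 ± 0.42) and LBD37 (2.53 ± 0.41), the BTB domain genes BT1 (4.11 ± 0.60) and BT2 (4.12 ± 0.48), and the protein kinase gene CIPK3 (2.77 ± 0.27). Large rises outside the nitrate response list included the signalling peptide genes CLE4 (4.56 ± 0.60) and CLE1 (3.69 ± 0.45), the sulfate transporter family gene SULTR3;5 (3.56 ± 0.35) and the potassium channel gene SKOR (3.29 ± 0.41), which loads potassium into the xylem. Of 14 cytokinin genes 7 were higher and 0 lower (12 and 0 adjusted over the list alone, 12 and 0 with the replicate block), among them the synthesis genes IPT3 (2.74 ± 0.37), CYP735A1 (1.86 ± 0.24) and CYP735A2 (2.35 ± 0.47) and the response regulator gene ARR9 (1.45 ± 0.26). The cytokinin list had a median of 1.47 and an adjusted camera p of 1e-15, but an adjusted p of 0.0554 with an estimated correlation. Among the vascular markers 2 of 13 were higher and 0 lower (12 and 0 adjusted over the list alone, 10 and 0 with the replicate block), namely SEOR1 (0.84 ± 0.16) and CalS7 (0.79 ± 0.19). Their median was 0.712, with an adjusted camera p of 2.86e-11, and an adjusted p of 0.0554 with an estimated correlation.

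Large falls in nitrate-fed roots included those of OCT1 (-6.39 ± 1.07), CHX17 (-5.37 ± 0.83) and CHX18 (-5.0 ± 0.28), which encode an organic cation transporter and cation/proton exchangers, the amino acid exporter family genes UMAMIT14 (-4.93 ± 0.70) and UMAMIT33 (-4.83 ± 0.55), the urea transporter gene DUR3 (-4.88 ± 0.31) and the high-affinity potassium transporter gene HAK5 (-3.91 ± 0.54). Of 19 nitrogen starvation and scavenging genes 6 were lower and 0 higher (10 and 1 adjusted over the list alone, 10 and 1 with the replicate block), among them DUR3, NRT2.4 (-2.78 ± 0.51), the peptide gene CLE3 (-3.24 ± 0.54), the glutamate dehydrogenase gene GDH2 (-1.27 ± 0.21) and the asparagine synthetase gene ASN1 (-2.76 ± 0.72, adjusted p = 0.0489). The list's median was -0.576, with an adjusted camera p of 1e-08, and 0.0384 with an estimated correlation. In ammonium assimilation 3 of 17 genes were higher, such as PPC2 (1.32 ± 0.22), and 5 lower, such as GLN1.3 (-0.69 ± 0.11) and GLU2 (-0.99 ± 0.20), with 3 and 7 adjusted over the list alone. Phosphate starvation genes had a median of -0.662, with 4 of 19 lower and 1 higher (9 and 1 adjusted over the list alone, 9 and 1 with the replicate block). SPX1 (-1.51 ± 0.28), AT5G03545 (-1.88 ± 0.38) and the sulfolipid synthase gene SQD2 (-0.77 ± 0.19) were lower and PHO1;H1 (2.15 ± 0.44) was higher. The adjusted camera p of this list was 7.77e-06, and the adjusted p 0.0554 with an estimated correlation. Nitrate transporters and channels went both ways, with 1 of 23 higher and 2 lower (7 and 5 adjusted over the list alone, 3 and 5 with the replicate block).

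Further lists passed camera at 0 min with the preset correlation only, or did not pass. Iron deficiency genes had a median of 0.58, which was 0.793 in scan batch 1 and -0.168 in scan batch 2 (adjusted camera p = 0.00333, adjusted p = 0.649 with an estimated correlation), with 1 of 26 higher (2 adjusted over the list alone, 3 with the replicate block), AT1G47400 (4.03 ± 1.03, well above background on only 1 of 3 ammonium-fed arrays, and 1.52 with normexp and the 75th percentile, adjusted p = 0.12), a gene for a short peptide of the iron deficiency response. Abscisic acid and dehydration genes had a median of -0.595 (adjusted camera p = 0.00114, adjusted p = 0.208 with an estimated correlation) and 0 of 17 called (3 lower adjusted over the list alone, 3 with the replicate block). Potassium transport had a median of 0.473 (adjusted camera p = 0.0146, adjusted p = 0.0696 with an estimated correlation and 0.0506 with the replicate block), with SKOR and KUP3 (0.48 ± 0.12) higher and HAK5 lower (4 and 1 adjusted over the list alone). Sulfate starvation had a median of 0.192 (adjusted camera p = 0.0247, adjusted p = 0.632 with an estimated correlation and 0.0758 with the replicate block) and SULTR4;2 (0.78 ± 0.20) higher (2 higher adjusted over the list alone, 2 higher and 1 lower with the replicate block). Root hair markers had a median of -0.374 (adjusted camera p = 0.0433, adjusted p = 0.662 with an estimated correlation), and RHD6 (-0.88 ± 0.17), a regulator of root hair initiation, was lower (1 adjusted over the list alone, 2 with the replicate block). Low oxygen and energy and sugar starvation genes did not pass as lists (camera, adjusted p = 0.352 and adjusted p = 0.82), although HB1 (2.73 ± 0.53), a non-symbiotic hemoglobin gene, and TPS10 (1.36 ± 0.17), of the trehalose phosphate synthase family, were higher. NRT2:1 (1.41 ± 0.48, adjusted p = 0.167) was not called, nor were the ammonium transporter genes AMT1;1 (-0.48 ± 0.18, adjusted p = 0.228) and AMT1;5 (-0.93 ± 0.32, adjusted p = 0.175), which passed with the replicate block (adjusted p = 0.0441 and 0.0174). Shoot photosynthesis markers had a median of -0.534 (camera, adjusted p = 0.352), endodermis markers one of -0.0686 (0.657) and dividing cell markers one of 0.0484 (0.579). In total 725 genes differed at an adjusted p under 0.05, 431 higher and 294 lower in nitrate-fed roots, of which 232 and 144 by at least 2-fold. With the replicate number as a block limma called 2214 genes (1155 higher, 1059 lower), with the scan batch as a block 1326, and in scan batch 1 alone 137, all of them with the same direction in scan batch 2 (137 of 137). Without ammonium-fed 0 min replicate 1 the count was 412, without nitrate-fed 0 min replicate 3 it was 413, and without nitrate-fed 0 min replicate 1 it was 481. The ammonium-fed 0 min arrays lay on slides 3, 3 and 6 and the nitrate-fed ones on slides 2, 1 and 4. They share no slide, so slide is mixed with feeding regime in this comparison, in both scan batches. The slide as a block gave 410 calls, and a fit of only the arrays compared gave 324. Of 44 called genes with values above, 10 lost their call in at least 1 fit with 1 array left out (ASN1, AT1G47400, AT5G03545, CYP735A2, CalS7, GLU2, KUP3, PHO1;H1, SQD2 and SULTR4;2). Normexp with the 75th percentile ended the calls of AT1G47400 and KUP3.

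After 15 min without N, genes of rapid responses to touch and stress had risen in ammonium-fed roots. ORA47 (AT1G74930), a transcription factor gene of the jasmonate pathway, was at least 37.3-fold higher. RRTF1 was higher (4.16 ± 0.69, well above background on only 1 of 3 arrays at 0 min, and 1.35 with normexp and the 75th percentile, adjusted p = 0.0665). CBF2, a regulator of cold responses, rose by 3.81 ± 0.78, the zinc finger gene STZ by 3.40 ± 0.51 and WRKY40 by 3.09 ± 0.54. NUDT4 (3.29 ± 0.28, adjusted p = 2.3e-05) had the smallest p of this comparison. Of the 20 touch and stress genes 9 had risen and 0 had fallen (17 and 0 adjusted over the list alone, 16 and 0 with the replicate block), with a median of 1.89, an adjusted camera p of 4.47e-52, and 0.00068 with an estimated correlation. SZF1 (2.2 ± 0.35) belonged to this list. Outside the lists CBF4 was at least 13.7-fold higher with the main values. This bound did not hold with normexp and the 75th percentile (log2 0.77, adjusted p = 0.822). The mitochondrial carrier gene DIC2 (3.21 ± 0.40) and the ethylene response factor genes ERF104 (2.91 ± 0.40) and ERF11 (2.62 ± 0.33) also rose. The deadenylase gene CAF1a (2.66 ± 0.31) and SRO5 (2.81 ± 0.47) rose as well.

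The jasmonate list had a median of 0.676 in these roots, with 1 of 19 genes called, JAZ1 (1.61 ± 0.23), a repressor of jasmonate signalling, 7 adjusted over the list alone and 7 with the replicate block. Its adjusted camera p was 2.05e-17, and 0.00629 with an estimated correlation. Only RABA4D, at least 13.9-fold lower (but -1.05 with normexp and the 75th percentile, adjusted p = 0.116), carried a symbol and full separation of arrays among the 3 genes that fell. None of the 12 N transport and assimilation genes chosen in advance was called, and their log2 fold changes lay between -0.14 (AMT1;5) and 0.41 (LBD37). The nitrate response list had a median of 0.0386 (adjusted camera p = 0.0211, adjusted p = 0.746 with an estimated correlation). Shoot photosynthesis markers had a median of -0.647 (adjusted camera p = 0.0667, and 0.000861 with the replicate block), endodermis markers one of 0.255 (0.0117, adjusted p = 0.448 with an estimated correlation) and dividing cell markers one of -0.129 (-0.264 in scan batch 1 and 0.105 in scan batch 2, 0.0417, adjusted p = 0.746 with an estimated correlation and 0.0766 with the replicate block). In total 93 genes were called, 90 higher and 3 lower. With the replicate block the count was 272 (254 higher, 18 lower), and in scan batch 1 alone 8, of which 8 had the same direction in scan batch 2. Without ammonium-fed 15 min replicate 2 the count was 26, and without ammonium-fed 0 min replicate 1 or 2 it was 34 or 53. It was 42 with the slide as a block and 14 with only the arrays compared. Of 15 called genes with values above, 6 lost their call in at least 1 fit with 1 array left out (CBF2, CBF4, RRTF1, SRO5, SZF1 and WRKY40). Normexp with the 75th percentile ended those of RRTF1, CBF4 and RABA4D.

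Nitrate-fed roots showed a similar rise after 15 min without N. ORA47 was at least 38.6-fold and RRTF1 at least 34.3-fold higher, and CBF2 (4.86 ± 0.78), CBF1 (4.55 ± 0.85), WRKY40 (3.14 ± 0.54) and STZ (2.92 ± 0.51) rose. Of the 20 touch and stress genes 8 had risen and 0 had fallen (17 and 0 adjusted over the list alone, 16 and 0 with the replicate block), including the calmodulin-like genes TCH2 (1.8 ± 0.22) and CML38 (2.78 ± 0.52) and the cell wall enzyme gene TCH4 (2.18 ± 0.33). The list's median was 1.74, and its adjusted p 0.000291 with an estimated correlation. Of 19 jasmonate genes 4 had risen (11 adjusted over the list alone, 10 with the replicate block), namely JAZ1 (2.03 ± 0.23), JAZ8 (3.08 ± 0.60, well above background on only 1 of 3 arrays at 0 min, and 0.76 with normexp and the 75th percentile, adjusted p = 1), JAZ6 (1.28 ± 0.27) and the transcription factor gene MYC2 (1.02 ± 0.20). That list's median was 0.892, and its adjusted p 0.000291 with an estimated correlation. NUDT4 (2.94 ± 0.28), DIC2 (2.82 ± 0.40), the peptide gene RTFL12 (2.86 ± 0.32) and AT4G27652 (2.91 ± 0.26, adjusted p = 4.27e-05), the gene with the smallest p, rose as well.

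LBD37 (AT5G67420), a nitrate-induced repressor of N uptake and assimilation genes, had fallen by then (-2.03 ± 0.41, adjusted p = 0.0408), as had the peptide genes RTFL17 (-1.11 ± 0.21) and RTFL16 (-0.97 ± 0.15). LBD37 was the only called member of the nitrate response list, which had 6 lower and 0 higher adjusted over the list alone and a median of -0.358 (adjusted camera p = 1.57e-19, and 0.0308 with an estimated correlation). Its call was lost whichever of the 6 arrays was left out. The other 11 N genes chosen in advance were not called and lay between -1.19 (HRS1) and 1.22 (ASN1). Nitrate transporters and channels had a median of -0.129 (adjusted camera p = 0.00718, adjusted p = 0.307 with an estimated correlation), cytokinin genes one of -0.318 (0.000698, adjusted p = 0.693 with an estimated correlation) and dividing cell markers one of 0.139 (0.00281, adjusted p = 0.672 with an estimated correlation). Shoot photosynthesis markers had a median of 0.566 (camera, adjusted p = 0.0865, and 0.0102 with the replicate block). In total 90 genes were called, 83 higher and 7 lower. With the replicate block the count was 248 (211 higher, 37 lower), in scan batch 1 alone it was 1, and with only the arrays compared in the fit it was 0 (723 at an unadjusted p under 0.05). Without nitrate-fed 15 min replicate 3 the count was 27, and without nitrate-fed 0 min replicate 3 or 1 it was 35 or 44. The slide as a block gave 34 calls. Of 20 called genes with values above, 11 lost their call in at least 1 fit with 1 array left out (CBF1, CBF2, CML38, JAZ6, JAZ8, LBD37, MYC2, RTFL16, RTFL17, STZ and WRKY40). With normexp and the 75th percentile JAZ8 and MYC2 were not called.

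Both feeding regimes shared 61 of their 15 min calls, all higher, where independent lists would share 0.28, and 0 genes were called in opposite directions. These comparisons have no array in common. With 1 array left out the shared count ranged from 24 to 63. It was 29, 39 and 40 without ammonium-fed 0 min replicates 1, 2 and 3, 24 without ammonium-fed 15 min replicate 2, 37 and 27 without nitrate-fed 0 min replicates 1 and 3, and 24 without nitrate-fed 15 min replicate 3. The replicate block gave 150 shared genes, the slide as a block 15, scan batch 1 alone 1 and only the arrays compared 0. In the test of the difference between both 15 min responses limma called 0 genes (384 at an unadjusted p under 0.05, where chance gives 1336). The count was 0 with the replicate block (1343 unadjusted) and 1 with normexp and quantile normalization. LBD37 differed by -2.45 ± 0.58, adjusted p = 1, and RABA4D had the smallest p (5.37 ± 1.01, adjusted p = 1).

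The N-supplied controls at 15 min had also been moved to fresh solution, but with N still present. They hold replicates 2 and 3 only, with 1 array in each scan batch. The groups at 0 min and at 15 min without N hold 2 arrays in scan batch 1 and 1 in scan batch 2. Scan batch is therefore partly mixed with every comparison against these controls. ORA47 was at least 43.7-fold higher in the ammonium-fed control than at 0 min and at least 30.6-fold higher in the nitrate-fed control (n = 2 against 3), where normexp and the 75th percentile ended its call. DIC2 was not called in the ammonium-fed control with that correction either. In the ammonium-fed control CBF4 was at least 28.3-fold higher (but 1.83 with normexp and the 75th percentile, adjusted p = 0.0554) and RRTF1 (4.27 ± 0.77, well above background on only 1 of 3 arrays at 0 min, and 1.66 with normexp and the 75th percentile, adjusted p = 0.0844), NUDT4 (2.83 ± 0.31), DIC2 (2.45 ± 0.45), CAF1a (2.19 ± 0.35) and JAZ1 (1.50 ± 0.25) rose. In the nitrate-fed control RRTF1 was at least 20.2-fold higher (but 1.23 with normexp and the 75th percentile, adjusted p = 0.481) and RTFL12 (2.92 ± 0.35), NUDT4 (2.67 ± 0.31), DIC2 (2.63 ± 0.45), JAZ1 (1.87 ± 0.25), TCH2 (1.42 ± 0.25) and AT4G29780 (3.18 ± 0.34) rose. The touch and stress list had a median of 1.43 in the ammonium-fed control (adjusted p = 0.00273 with an estimated correlation) and of 1.4 in the nitrate-fed control (0.00311), and the jasmonate list 0.75 (0.00733) and 0.668 (0.00464). Of the touch and stress genes 1 and 2 were called (15 and 12 adjusted over the list alone), and of the jasmonate genes 1 and 1 (7 and 11 adjusted over the list alone). In total 25 genes were called in the ammonium-fed control and 24 in the nitrate-fed control, all higher (25 of 25 and 24 of 24). These counts did not hold in every fit, since limma called 0 and 0 with the slide as a block (930 and 869 at an unadjusted p under 0.05), 0 and 0 in scan batch 1 alone (1564 and 861) and 0 and 2 with only the arrays compared (803 unadjusted for the ammonium-fed control), and 40 and 33 with the scan batch as a block. The 83 genes called higher in nitrate-fed roots without N had a median of 1.6 in ammonium-fed roots without N and of 1.42 in the ammonium-fed control, where 83 of 83 were higher than at 0 min. The 90 genes called higher in ammonium-fed roots had medians of 1.4 and 1.41 in nitrate-fed roots without N and in their control. Without replicate 2 of the ammonium-fed control its count was 2, and without ammonium-fed 0 min replicate 1 it was 9. Without replicate 2 of the nitrate-fed control its count was 6, and without nitrate-fed 0 min replicate 3 or 1 it was 9 or 12. In fits with 1 array left out at least once, 6 of 7 called genes with values above lost their call in the ammonium-fed control and 4 of 8 in the nitrate-fed control.

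Roots without N for 15 min were also set against these controls directly. No gene passed (0 called) in ammonium-fed roots, with 870 at an unadjusted p under 0.05, or in nitrate-fed roots, with 208. Chance gives 1336 in each, so both lie below it, and 0 calls do not show that no gene differed. With the replicate block 2529 and 594 lay under 0.05, and again 0 and 0 were called. The gene with the smallest p was IDD1 in ammonium-fed roots (1.39 ± 0.24, adjusted p = 0.348) and AT1G60750 in nitrate-fed roots (-1.36 ± 0.30, adjusted p = 1). LBD37 differed by -0.96 ± 0.46 in ammonium-fed and by -1.68 ± 0.46 in nitrate-fed roots. The other 11 N genes chosen in advance lay between -0.49 (HRS1) and 0.36 (ASN1) in ammonium-fed roots and between -0.85 (HRS1) and 0.24 (NRT2:1) in nitrate-fed roots. No list passed in either comparison with an estimated correlation. In nitrate-fed roots iron deficiency genes had a median of -0.873 (adjusted camera p = 6.8e-21, adjusted p = 0.152 with an estimated correlation), anthocyanin and flavonoid genes one of 1.18 (1.67e-05, adjusted p = 0.224 with an estimated correlation) and shoot photosynthesis markers one of 1.37 (5.23e-11, adjusted p = 0.354 with an estimated correlation). In ammonium-fed roots the shoot photosynthesis markers had a median of 0.795 (0.00323, adjusted p = 0.996 with an estimated correlation). For ammonium-fed roots the other settings called between 0 and 5 genes, the highest without control replicate 3, and 1 without ammonium-fed 15 min replicate 3 and 1 in scan batch 1 alone. For nitrate-fed roots they called between 0 and 3, the highest without control replicate 3, and 1 with normexp and quantile normalization.

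**Figure D1:**
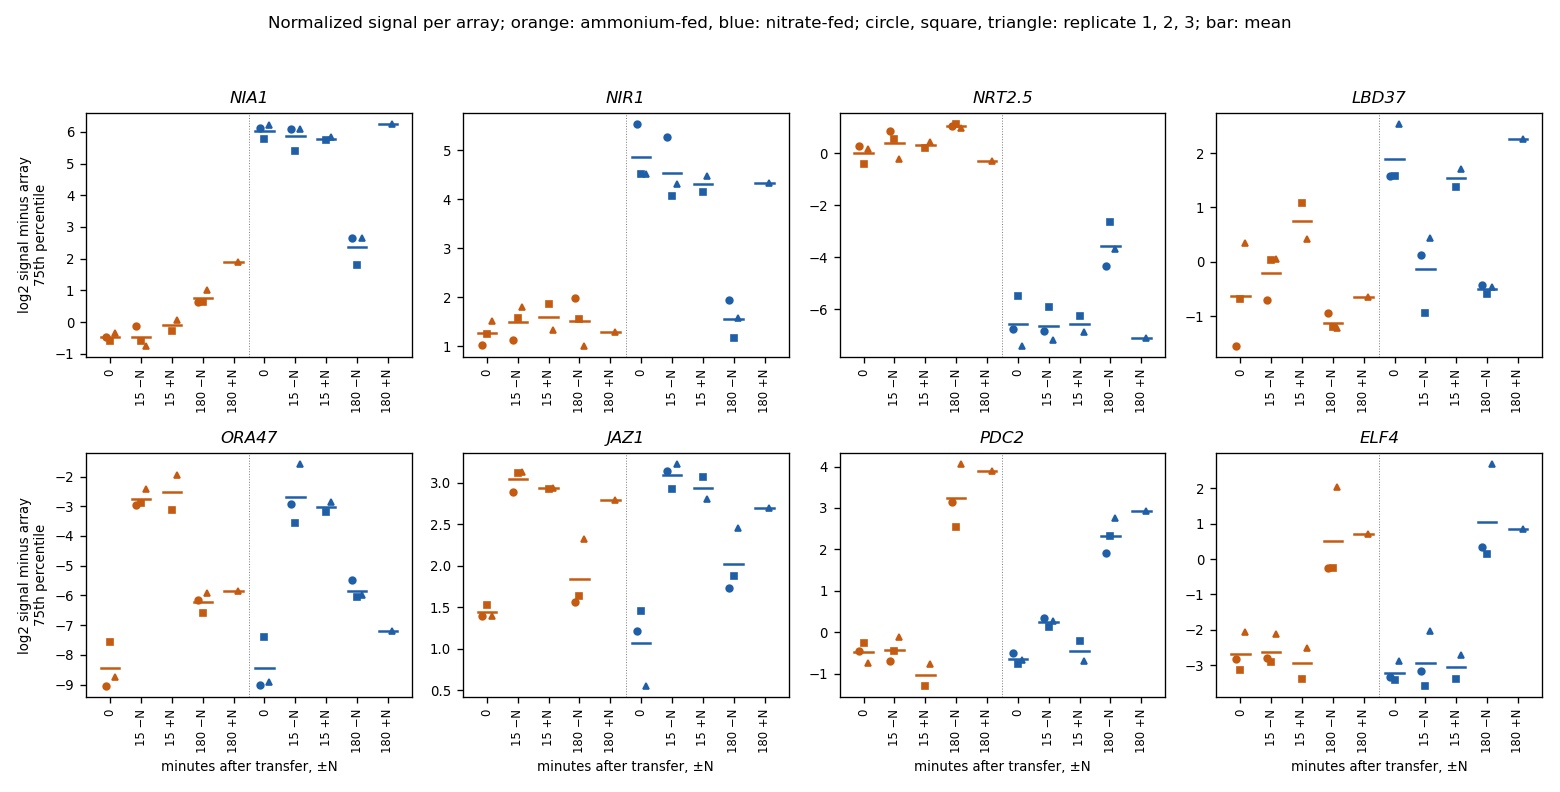
Log2 signal minus the 75th percentile of the array (y axis) for 8 genes in each group (x axis, minutes after transfer with or without N), with 1 point per array and a bar at the group mean. ORA47 and JAZ1 were higher at 15 min with and without N, NIA1, NIR1 and LBD37 were lower after 180 min without N in nitrate-fed roots, and PDC2 and ELF4 were higher after 180 min in both feeding regimes.

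After 180 min without N, genes of the low oxygen response were higher in ammonium-fed roots. ADH1, which encodes alcohol dehydrogenase, rose by 5.46 ± 0.98, the pyruvate decarboxylase gene PDC2 (AT5G54960) by 3.73 ± 0.29, adjusted p = 1.16e-05, the hemoglobin gene HB1 (AT2G16060) by 4.46 ± 0.53 and the aquaporin family gene NIP2;1 by 6.94 ± 1.04. SRO4 was at least 128-fold higher. All 10 measured low oxygen genes had risen (10 adjusted over the list alone), among them the sucrose synthase genes SUS4 (3.40 ± 0.42) and SUS1 (2.87 ± 0.33) and the ethylene receptor gene ETR2 (2.90 ± 0.38). The list had a median of 3.31, an adjusted camera p of 1.4e-31, and 0.0127 with an estimated correlation. Its median was 2.74 in scan batch 1 and 4.68 in scan batch 2.

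Clock genes changed in both directions between 0 and 180 min in these roots, and time of day was not separated from the time without N. In replicate 3 their median was -0.29 without N and -0.20 in the N-supplied control, with 7 and 8 of 17 higher. As members went both ways, these medians cannot compare the clock with and without N. Of the 17 clock genes measured 5 had risen and 3 had fallen (7 and 7 adjusted over the list alone). The evening genes ELF4 (3.18 ± 0.65), PCL1 (2.08 ± 0.31) and GI (1.18 ± 0.21) rose, and RVE8 (-2.76 ± 0.43), LCL1 (-0.94 ± 0.20) and AT3G54500 (-2.77 ± 0.28) fell. The photoperiod gene FKF1 rose by 4.28 ± 0.83, while CDF1 (-1.64 ± 0.35) and CDF3 (-1.22 ± 0.15) fell. Both nitrate reductase genes rose, NIA2 by 1.46 ± 0.21, adjusted p = 0.00214 and NIA1 by 1.22 ± 0.23, adjusted p = 0.0167, and LBD38 fell (-1.60 ± 0.28). The single N-supplied control array at 180 min, in scan batch 2, had both nitrate reductase genes higher still. Without N minus control, NIA1 differed by -1.14 and NIA2 by -0.61. The rise of these genes was therefore not separated from time in the solution. No other member of the nitrate response list was called (3 and 3 adjusted over the list alone), and the list had a median of -0.144 (camera, adjusted p = 0.805). CML38 rose by 4.26 ± 0.52 and was the only called touch and stress gene (3 higher adjusted over the list alone, 5 with the replicate block). That list had a median of 0.784 (adjusted camera p = 1.69e-09, adjusted p = 0.272 with an estimated correlation). The jasmonate synthesis gene AOC1 rose by 1.27 ± 0.26 (list median 0.339, adjusted camera p = 0.00167, adjusted p = 0.603 with an estimated correlation). SULTR1;3 fell by 1.23 ± 0.26 on the log2 scale, and RABA4D was at least 9.26-fold lower (but -0.63 with normexp and the 75th percentile, adjusted p = 0.453). The other 10 N genes chosen in advance were not called and lay between -0.63 (NRT1.1) and 1.03 (NRT2.5). In total 211 genes were called, 164 higher and 47 lower (104 and 24 by at least 2-fold). With the replicate block the count was 1072 (694 higher, 378 lower), with the scan batch as a block 451 and in scan batch 1 alone 28, of which 27 had the same direction in scan batch 2. Without ammonium-fed 180 min replicate 3 the count was 85, and without ammonium-fed 0 min replicate 2 or 1 it was 86 or 111. It was 64 with the slide as a block and 16 with only the arrays compared. Of 23 called genes with values above, 10 lost their call in at least 1 fit with 1 array left out (ADH1, AOC1, ELF4, FKF1, GI, LBD38, LCL1, NIA1, RABA4D and SULTR1;3). With normexp and the 75th percentile AOC1 and RABA4D were not called.

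After 180 min without N, nitrate assimilation genes had fallen in nitrate-fed roots. NIA1 fell by 3.68 ± 0.23 on the log2 scale (adjusted p = 4.13e-07), NIR1 by 3.30 ± 0.34 and NIA2 by 1.23 ± 0.21. The uroporphyrinogen methyltransferase gene UPM1 (-3.11 ± 0.64, well above background on only 1 of 3 arrays at 180 min, and -1.15 with normexp and the 75th percentile), whose product makes part of the nitrite reductase cofactor, and the glucose-6-phosphate dehydrogenase gene G6PD3 (-3.19 ± 0.49) fell too. NRT2.5 was higher (3.01 ± 0.46, adjusted p = 0.00172), but it lay well above background on only 1 of 3 arrays at 0 min and was not called with normexp background correction (adjusted p = 0.0982 with the 75th percentile and 0.111 with quantile normalization). Of the 31 nitrate response genes 23 had fallen and 0 had risen (29 and 0 adjusted over the list alone), with a median of -1.69, an adjusted camera p of 3.74e-60, and 0.000603 with an estimated correlation. The median was -1.75 in scan batch 1 and -1.70 in scan batch 2. Further members were NRT1.1 (-1.79 ± 0.29), LBD37 (-2.40 ± 0.41), HRS1 (-2.25 ± 0.42), CIPK3 (-2.27 ± 0.27) and the transcription factor gene TGA1 (-1.36 ± 0.14).

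Other N genes fell as well. Among nitrate transporters and channels WR3 (-1.40 ± 0.30), the partner protein gene of the NRT2 transporters, and CLC-B (-1.01 ± 0.18) fell with NRT1.1, giving 3 lower and 1 higher of 23 (7 and 1 adjusted over the list alone, list median -0.365, adjusted camera p = 0.00126, adjusted p = 0.141 with an estimated correlation). Of 17 ammonium assimilation genes 4 fell (8 lower and 4 higher adjusted over the list alone), the glutamine synthetase genes GS2 (-1.22 ± 0.18) and GSR2 (-1.10 ± 0.20), the glutamate synthase gene GLT1 (-1.21 ± 0.22) and PPC3 (-2.02 ± 0.41). GLN1;4 (0.60 ± 0.13) rose. That list had a median of -0.302 (adjusted camera p = 0.000945, adjusted p = 0.0819 with an estimated correlation). In nitrogen starvation and scavenging NRT2.5 and GLN1;4 rose (2 of 19, 8 adjusted over the list alone, 5 higher and 2 lower with the replicate block), with a list median of 0.27 (adjusted camera p = 0.0231, adjusted p = 0.465 with an estimated correlation and 0.0812 with the replicate block). ASN1 (2.24 ± 0.72, adjusted p = 0.183), NRT2:1 (-1.34 ± 0.48), NRT2.4 (-0.05 ± 0.51), AMT1;1 (0.48 ± 0.18) and AMT1;5 (-0.48 ± 0.32) were not called. IPT3 (-1.98 ± 0.37) and ARR9 (-1.16 ± 0.26) fell, 2 of 14 cytokinin genes (8 adjusted over the list alone, 9 with the replicate block), with a list median of -1.06 (adjusted camera p = 8.74e-10, adjusted p = 0.141 with an estimated correlation). The peptide gene CLE4 fell by 4.15 ± 0.60 on the log2 scale. Among genes for other ions, SKOR (-2.52 ± 0.41), KT1 (-0.82 ± 0.15), a potassium uptake channel, SULTR1;2 (-2.17 ± 0.34) and PHO1;H1 (-2.52 ± 0.44) fell and SPX1 (1.49 ± 0.28) rose. Any change in the potassium given with the nitrate was not separated from the loss of nitrate. Potassium transport had a median of -0.0715 (adjusted camera p = 0.00583, adjusted p = 0.0819 with an estimated correlation and 0.0577 with the replicate block), sulfate starvation one of -0.201 (-0.392 in scan batch 1 and 0.0295 in scan batch 2, 0.0231, adjusted p = 0.478 with an estimated correlation and 0.0577 with the replicate block) and phosphate starvation one of 0.193 (0.0816, with 4 higher and 1 lower of 19 adjusted over the list alone and 5 and 1 with the replicate block).

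Clock genes changed in nitrate-fed roots too, with 5 higher and 6 lower of 17 (6 and 7 adjusted over the list alone), again without a separation from time of day. Their median in replicate 3 was -0.21 without N and -0.16 in the N-supplied control. Members went both ways (8 of 17 higher in each), so these medians cannot compare the clock with and without N. CCA1 (-4.47 ± 1.05), LHY (-3.91 ± 0.88), RVE8 (-2.79 ± 0.43) and AT3G54500 (-2.75 ± 0.28) fell and ELF4 (4.27 ± 0.65), TOC1 (1.38 ± 0.21) and FKF1 (4.92 ± 0.83, well above background on only 2 of 3 arrays at 0 min, and 3.13 with normexp and the 75th percentile) rose. Of the 8 clock genes called in both feeding regimes, 8 had the same direction, 5 higher and 3 lower. PDC2 rose by 2.97 ± 0.29 and SUS1 by 1.4 ± 0.33, the only called member of the low oxygen list of 10 (3 adjusted over the list alone). The low oxygen list had a median of 1.02 (adjusted camera p = 0.00206, adjusted p = 0.478 with an estimated correlation), which was 0.0615 in scan batch 1 and 2.15 in scan batch 2. The abscisic acid synthesis gene NCED3 (1.18 ± 0.22), ABF1 (2.44 ± 0.47), AOC1 (2.16-fold), JAZ1 (0.95 ± 0.23), CML38 (2.56 ± 0.52) and HCAR (2.5 ± 0.31), a gene of chlorophyll turnover, also rose, and TPS10 (-1.0 ± 0.17) fell. Jasmonate genes had a median of 0.478 (2 of 19 called, 4 adjusted over the list alone, 4 with the replicate block, adjusted camera p = 4.8e-05, adjusted p = 0.141 with an estimated correlation), touch and stress genes 0.713 (1 of 20 called, 2 adjusted over the list alone, 3 with the replicate block, 0.00109, adjusted p = 0.465 with an estimated correlation), abscisic acid and dehydration genes 0.515 (1 of 17 called, 1 adjusted over the list alone, 3 with the replicate block, 0.0384, adjusted p = 0.478 with an estimated correlation) and shoot photosynthesis markers 0.806 (0.0462, adjusted p = 0.754 with an estimated correlation). In total 434 genes were called, 197 higher and 237 lower (110 and 163 by at least 2-fold). With the replicate block the count was 1493 (802 higher, 691 lower), with the scan batch as a block 701 and in scan batch 1 alone 58, of which 57 had the same direction in scan batch 2. Without nitrate-fed 0 min replicate 1 the count was 271, and without nitrate-fed 180 min replicate 2 or 3 it was 283 or 286. Fewer were called with the slide as a block (265) and with only the arrays compared (75). Of 42 called genes with values above, 15 lost their call in at least 1 fit with 1 array left out (ABF1, AOC1, ARR9, CCA1, CML38, GLN1;4, HRS1, IPT3, JAZ1, LHY, NCED3, PPC3, SUS1, UPM1 and WR3). The calls of NRT2.5, CCA1, NCED3, AOC1 and JAZ1 ended with normexp and the 75th percentile.

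The difference between both 180 min responses asked which genes changed differently from 0 to 180 min without N in the 2 feeding regimes. It holds the time in the solution as well as the loss of ammonium or nitrate. It also holds any change in the potassium or sulfate given with them. Nitrate assimilation genes fell in nitrate-fed relative to ammonium-fed roots, NIA1 by 4.90 ± 0.33 on the log2 scale (adjusted p = 1.06e-06), NIR1 by 3.55 ± 0.48 and NIA2 by 2.69 ± 0.30. HB1 (-5.43 ± 0.75), the boron exporter gene BOR1 (-2.48 ± 0.26), CIPK3 (-2.26 ± 0.38), MDAR6 (-1.56 ± 0.25), AAE3 (-1.51 ± 0.24) and ATB2 (-0.93 ± 0.14) had negative differences too. NIA1, NIA2 and BOR1 were the 3 genes called at 180 min in opposite directions, higher in ammonium-fed and lower in nitrate-fed roots. The call of NIA1 in ammonium-fed roots was lost in at least 1 fit with 1 array left out. NIA1 and NIA2 were higher on the single ammonium-fed N-supplied control array than without N. Their rise in ammonium-fed roots was thus not separated from time in the solution. BOR1 changed by 0.90 and -1.58. Of the nitrate response genes 4 of 31 were called lower (24 adjusted over the list alone, 9 with the replicate block), with a median of -1.59 (adjusted camera p = 1.69e-67, and 0.000326 with an estimated correlation). Of the low oxygen genes 1 of 10, HB1, was called lower (10 adjusted over the list alone), with a list median of -2.76 (adjusted camera p = 9.92e-26, and 0.0154 with an estimated correlation). HB1 was already higher in nitrate-fed roots at 0 min (2.73 ± 0.53), so its responses started from unlike levels. Potassium transport had a median of -0.241 (0.00312, and 0.0405 with an estimated correlation). NRT2.5 (1.98 ± 0.66, adjusted p = 0.718), HRS1 (-2.37 ± 0.60, adjusted p = 0.272), LBD37 (-1.91 ± 0.58, adjusted p = 0.552) and NRT1.1 (-1.16 ± 0.41) were not called. In total 20 genes were called, 1 higher and 19 lower, against 2 with the slide as a block and 10 with only the arrays compared. Of 9 called genes with values above, 3 lost their call in at least 1 fit with 1 array left out (AAE3, CIPK3 and MDAR6). Both feeding regimes shared 94 calls at 180 min in the same direction, 71 higher and 23 lower, where independent lists would share 1.21 and 0.417. The shared calls were 34 with the slide as a block, 15 in scan batch 1 alone and 2 with only the arrays compared. These comparisons have no array in common. With the replicate block limma called 94 genes for the difference (14 higher, 80 lower) and 429 shared genes, with the scan batch as a block 42 genes, and in scan batch 1 alone 1, with the same direction in scan batch 2. Leaving out nitrate-fed 0 min replicate 1 gave 12 genes for the difference, and leaving out ammonium-fed 0 min replicate 1 or 2, ammonium-fed 180 min replicate 1 or nitrate-fed 180 min replicate 3 gave 13 each, while the shared calls were 35, 40, 56 and 62 without ammonium-fed 0 min replicate 2, ammonium-fed 180 min replicate 3, ammonium-fed 0 min replicate 1 and nitrate-fed 180 min replicate 3.

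Roots without N for 180 min were set against the single N-supplied control array of their feeding regime (n = 3 against 1, the control being assumed to vary like the other groups). The control lay in scan batch 2 and 2 of the 3 arrays without N in scan batch 1, so scan batch is mixed with N supply here. In nitrate-fed roots NIA1 was lower than in the control by -3.89 ± 0.33, adjusted p = 3.76e-05, NIR1 by -2.77 ± 0.48, NIA2 by -1.72 ± 0.30 and BOR1 by -2.35 ± 0.26. NRT2.5 was at least 11.2-fold higher than on the control array, where it was not well above background (but 0.81 with normexp and the 75th percentile, adjusted p = 0.897), and the ammonium transporter gene AMT1;1 higher by 1.46 ± 0.25. CIPK3 (-2.28 ± 0.38), CIPK23 (-1.20 ± 0.21), TPS10 (-1.30 ± 0.24), SAG21 (-3.13 ± 0.55), LEA3 (-3.07 ± 0.55), AAE3 (-1.61 ± 0.24) and MDAR6 (-1.45 ± 0.25) were lower. LBD37 (-2.76 ± 0.58, adjusted p = 0.0879) and HRS1 (-2.56 ± 0.60, adjusted p = 0.166) were not called. The nitrate response list had 5 of 31 lower (21 adjusted over the list alone) and a median of -1.57 (adjusted camera p = 1.54e-40, and 0.0043 with an estimated correlation). Nitrogen starvation and scavenging had 2 of 19 higher (4 higher and 1 lower adjusted over the list alone) and a median of 0.555 (0.0084, adjusted p = 0.312 with an estimated correlation). Low oxygen genes had a median of -2.03 (2.89e-12, adjusted p = 0.185 with an estimated correlation; 6 lower adjusted over the list alone), sulfate starvation genes one of 1.49 (4.27e-07, adjusted p = 0.204 with an estimated correlation) and shoot photosynthesis markers one of 1.85 (3.16e-05, adjusted p = 0.365 with an estimated correlation). In total 36 genes were called, 15 higher and 21 lower, but limma called 1 with the slide as a block and 0 with only the arrays compared (857 at an unadjusted p under 0.05), and 64 with the scan batch as a block. More genes were called with the authors' value table and with normexp and quantile normalization, and fewer with normexp and the 75th percentile. Of the calls 22.7%, 17.1% and 29.0% were higher in these settings, against 41.7%. Without nitrate-fed 180 min replicate 3 the count was 10 and without replicate 1 it was 20. Of 13 called genes with values above, 10 lost their call in at least 1 fit with 1 array left out (AMT1;1, CIPK23, CIPK3, LEA3, MDAR6, NIA2, NIR1, NRT2.5, SAG21 and TPS10).

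In ammonium-fed roots the same comparison called 0 genes (902 at an unadjusted p under 0.05), with 3 by normexp and the 75th percentile, 11 by normexp and quantile normalization and 6 by the authors' value table. DGR1 had the smallest p (-1.72 ± 0.28, adjusted p = 0.355). NIA1 differed by -1.14 ± 0.33, adjusted p = 0.986 and NRT2.5 by 1.35 ± 0.66, and the other 10 N genes chosen in advance lay between -1.21 (ASN1) and 0.99 (NRT2:1). No list passed with an estimated correlation. Jasmonate genes had a median of -0.641 (adjusted camera p = 1.96e-09, adjusted p = 0.121 with an estimated correlation), low oxygen genes one of -0.71 (0.00891, adjusted p = 0.609 with an estimated correlation) and shoot photosynthesis markers one of 1.55 (0.00191, adjusted p = 0.609 with an estimated correlation). Without ammonium-fed 180 min replicate 3 the count was 6.

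**Figure D2:**
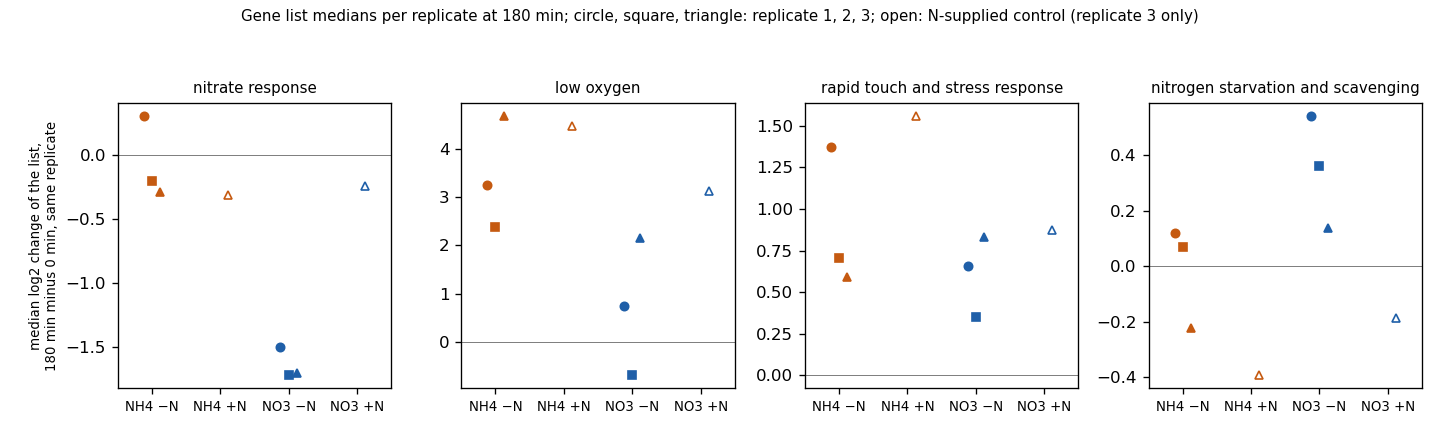
Median log2 change of 4 gene lists from 0 to 180 min within each replicate (y axis), by feeding regime and N supply (x axis). Nitrate response genes lay between -1.72 and -1.50 in the 3 replicates of nitrate-fed roots without N and at -0.24 in the N-supplied control, and low oxygen genes lay at 4.68 and 4.48 in replicate 3 of ammonium-fed roots without and with N.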

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

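The tests of the 3 patterns weighed first were all chosen after the results were seen, and the counts of other splits of the samples were planned. The scan batch test of the first pattern was settled when scan batch 1 alone had called only 1 gene in nitrate-fed roots at 15 min, so it used the 50 genes with the largest t there.

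The first pattern is the rise of touch, stress and jasmonate genes after 15 min without N. Loss of the N supply as the whole cause is argued against by the controls, since the 83 genes called in nitrate-fed roots were higher in ammonium-fed roots without N than in their control by only 0.12 of their rise (median 0.19 of 1.6). A constant shift between scan batches cancels by design, since nitrate-fed roots had 2 arrays in scan batch 1 and 1 in scan batch 2 at both times. The rise also recurred in scan batch 2. The 50 genes picked in scan batch 1 (median 1.82) of nitrate-fed roots had a median of 2.22 there, with 50 of 50 higher. Handling during the transfer stays open and may account for most of the rise, since the same 83 genes rose in the N-supplied control by 0.887 of their rise without N, and in the reverse test the ratio was 1.01 for 90 genes. A smaller rise beyond handling stays open, since 62 of the 83 and 71 of the 90 genes were higher without N than in the control (0.12 and 0.113 of the rise). The controls hold replicates 2 and 3 only, so all these shares and ratios are partly mixed with scan batch.

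The second pattern is the rise of low oxygen genes after 180 min in ammonium-fed roots. A single replicate as its source is argued against, since the list median was over 1 in 3 of 3 replicates (3.25, 2.39 and 4.68). So is the scaling, since normexp with quantile normalization, which changed background correction and scaling together, kept 0.963 of the median. Time or conditions in the solution, whatever its N, cannot be told apart from loss of N with 1 control array, but may be the source. In replicate 3 the median of the N-supplied control was 0.957 of that without N (4.48 against 4.68). It lay at percentile 100 of 10000 random lists matched on expression. Random lists lack the correlation between members of this list (estimated at 0.784), so the percentile is no test. In nitrate-fed roots the same list rose more in the control (3.12) than without N (2.15) in replicate 3. The rise was larger in ammonium-fed roots by the test of the difference, and what set both regimes apart was not tested.

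The third pattern is the fall of nitrate response genes after 180 min without N in nitrate-fed roots. Scaling is argued against, since normexp with quantile normalization, which changed background correction and scaling together, kept 0.936 of the median. Time of day or time in the solution, lowering these genes by a like log2 amount in both feeding regimes, is argued against as well. The list median in ammonium-fed roots at 180 min was 0.0851 of that in nitrate-fed roots (replicates from -0.29 to 0.30 against -1.72 to -1.50, camera adjusted p = 0.000326 for the difference with an estimated correlation). At 0 min 29 of 31 genes were well above background on all ammonium-fed arrays. A common cause that removes only the part of expression raised by nitrate is not covered. The list was already lower in ammonium-fed roots at 0 min (median 1.82 for nitrate-fed against ammonium-fed). Time of day or time in the solution acting in nitrate-fed roots only cannot be told apart from loss of the nitrate supply. The genes were already lower in ammonium-fed roots, and only 1 control array was measured. In replicate 3 the list median changed by -0.31 in the ammonium-fed control. In the nitrate-fed control it changed by -0.24, which was 0.142 of the change without N (-1.70). This lay at percentile 0 of random lists matched on expression, which lack the correlation between list members and give no test of that array. Loss of the nitrate supply stays open too, since the lower level without N than in the control (camera adjusted p = 0.0043 with an estimated correlation) rests on that array, whose spread was assumed.

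Comparisons of 3 against 3 arrays allow 10 splits, too few for a share under 0.05. For the differences, pairs of a 0 min and a later array with the same replicate number were moved between the feeding regimes, once the mean of each regime was taken out. This also gives 10 splits. The real split was the only one of 10 to call as many genes (1 of 10) for both regimes at 0 min (725), ammonium-fed roots at 15 min (93) and 180 min (211), nitrate-fed roots at 15 min (90) and 180 min (434) and the 180 min difference (20), and the highest other split called 0, except 2 for ammonium-fed roots at 180 min. For the 15 min difference all 10 of 10 splits called 0, the real one among them, so the splits decide nothing there. Among the 4 splits that part all 3 replicate pairs, the highest other called 0 in each comparison.

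The remaining results differed between the feeding regimes by the test of the difference itself. At 180 min 20 genes were called. Of those with a symbol, HB1 differed by -5.43, NIA1 by -4.90, NIR1 by -3.55, NIA2 by -2.69, BOR1 by -2.48, CIPK3 by -2.26, MDAR6 by -1.56, AAE3 by -1.51 and ATB2 by -0.93. At 180 min these lists passed camera with the preset correlation. The medians were -1.59 for the nitrate response, -2.76 for low oxygen, -0.241 for potassium transport, -1.03 for cytokinin, -0.0411 for nitrate transporters and channels, 0.191 for nitrogen starvation and scavenging, -0.0414 for ammonium assimilation, -0.431 for touch and stress, -0.179 for iron deficiency, 0.275 for phosphate starvation, 0.32 for abscisic acid and dehydration and -0.206 for vascular markers. With an estimated correlation only the nitrate response, low oxygen and potassium transport passed (3 of 12). The medians of nitrate transporters and channels (-0.190 and 0.0152), touch and stress (-0.552 and 0.131), iron deficiency (0.0207 and -0.395) and vascular markers (-0.341 and 0.0226) differed in sign between scan batches 1 and 2. At 15 min the medians of passing lists were -0.455 for the nitrate response, -0.197 for nitrate transporters and channels, 0.179 for jasmonate, -0.546 for iron deficiency, 1.05 for shoot photosynthesis markers, -0.3 for root hair markers (-0.855 and 0.351 in scan batches 1 and 2), -0.274 for endodermis markers, -0.197 for vascular markers and 0.307 for dividing cell markers. With an estimated correlation 0 of these 9 passed, and the lowest adjusted p was 0.0882 for the nitrate response.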

How the results depend on the processing

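The scan batch as a block and scan batch 1 alone were chosen after the data were seen, and all other settings here were planned. Of the 181 called values of named genes, 161 kept their call and direction with normexp and the 75th percentile, 164 with normexp and quantile normalization, 171 with the authors' value table, 176 without the filter on dim probes, 168 with the mean of all probes, 181 with the replicate block, 181 with the scan batch as a block, 95 with the slide as a block, 64 with only the arrays compared, 36 of the 168 that could be fitted in scan batch 1 alone and 106 whichever array was left out, and 0 changed direction in a fit that gave a value. Dropping the filter on dim probes and averaging all probes of a gene left every count within 1.5 times its main value. Normexp with the 75th percentile moved 1 count, to 3 (ammonium-fed 180 min against control). Normexp with quantile normalization gave 1 (the 15 min difference), 31 (the 180 min difference), 1 (nitrate-fed 15 min against control), 11 (ammonium-fed 180 min against control) and 76 (nitrate-fed 180 min against control), and the authors' value table gave 6 (ammonium-fed 180 min against control) and 75 (nitrate-fed 180 min against control). Normexp with the 75th percentile also shifted the median of all genes from -0.0125 to -0.115 for ammonium-fed 15 min against control, from 0.0408 to -0.0603 for ammonium-fed 180 min against control and from 0.0591 to -0.105 for nitrate-fed 180 min against control. With the replicate block, in the comparisons the numbers pair, the counts were 2214 (both regimes at 0 min), 272 (ammonium-fed 15 min), 1072 (ammonium-fed 180 min), 248 (nitrate-fed 15 min), 1493 (nitrate-fed 180 min), 94 (the 180 min difference), 150 (shared at 15 min) and 429 (shared at 180 min). The block ended list calls for jasmonate in the 15 min difference (adjusted p = 0.0672) and nitrate transporters in the 180 min difference (0.107), added calls for iron deficiency (0.017) and root hair markers (0.0245) in nitrate-fed roots at 15 min, abscisic acid genes in the 15 min difference (0.0385) and shoot photosynthesis markers in the 180 min difference (0.00879), and beyond those given with each comparison it changed no other call there. Comparisons with the controls have at most 2 pairs of arrays with the same number (correlations 0.336 to 0.672 at 15 min), too few for the check, and arrays with replicate number 3 also share scan batch 2. There the replicate block gave 1 (ammonium-fed 180 min against control), 141 (nitrate-fed 180 min against control), 77 (the ammonium-fed 15 min control) and 62 (the nitrate-fed 15 min control). The slide as a block gave 410 (both regimes at 0 min), 42 (ammonium-fed 15 min), 64 (ammonium-fed 180 min), 34 (nitrate-fed 15 min), 265 (nitrate-fed 180 min), 2 (the 180 min difference), 1 (nitrate-fed 180 min against control), 0 (the ammonium-fed 15 min control), 0 (the nitrate-fed 15 min control), 15 (shared at 15 min) and 34 (shared at 180 min). The scan batch as a block gave 1326 (both regimes at 0 min), 451 (ammonium-fed 180 min), 701 (nitrate-fed 180 min), 42 (the 180 min difference), 1 (ammonium-fed 180 min against control), 64 (nitrate-fed 180 min against control), 40 (the ammonium-fed 15 min control) and 169 (shared at 180 min), and scan batch 1 alone gave 137 (both regimes at 0 min), 8 (ammonium-fed 15 min), 28 (ammonium-fed 180 min), 1 (nitrate-fed 15 min), 58 (nitrate-fed 180 min), 1 (the 180 min difference), 1 (ammonium-fed 15 min against control), 0 (the ammonium-fed 15 min control), 0 (the nitrate-fed 15 min control), 1 (shared at 15 min) and 15 (shared at 180 min), with no value for the 180 min controls, which lie in scan batch 2. With only the arrays compared in the fit the counts were 324 (both regimes at 0 min), 14 (ammonium-fed 15 min), 16 (ammonium-fed 180 min), 0 (nitrate-fed 15 min), 75 (nitrate-fed 180 min), 10 (the 180 min difference), 0 (nitrate-fed 180 min against control), 0 (the ammonium-fed 15 min control), 2 (the nitrate-fed 15 min control), 0 (shared at 15 min) and 2 (shared at 180 min). Leaving out 1 array at a time gave 412 to 582 (both regimes at 0 min), 26 to 99 (ammonium-fed 15 min), 85 to 201 (ammonium-fed 180 min), 12 to 30 (the 180 min difference), 2 to 24 (the ammonium-fed 15 min control), 24 to 63 (shared at 15 min), 35 to 93 (shared at 180 min), 0 to 5 (ammonium-fed 15 min against control), 0 to 6 (ammonium-fed 180 min against control), 27 to 89 (nitrate-fed 15 min), 271 to 586 (nitrate-fed 180 min), 6 to 31 (the nitrate-fed 15 min control), 0 to 3 (nitrate-fed 15 min against control) and 10 to 32 (nitrate-fed 180 min against control), where a lone remaining control array was assumed to vary like the other groups. A count of 0 stayed 0 for the 15 min difference whichever array was left out. Where limma called 0 genes in the 15 min ammonium-fed and nitrate-fed controls, the unadjusted p was under 0.05 for 930 and 869 genes with the slide as a block and for 1564 and 861 in scan batch 1 alone. With only the arrays compared it was under 0.05 for 723 (nitrate-fed 15 min), 857 (nitrate-fed 180 min against control) and 803 (the ammonium-fed 15 min control). By construction, scan batch 1 alone, only the arrays compared and leaving out an array fit fewer samples. The cause of the other shifts was not tested. The direction of the list test changed in 7 list results that passed on at least 1 side, all against controls. Their medians under the alternative were, for the nitrate response in ammonium-fed 15 min against control with normexp and the 75th percentile -0.109, for root hair markers in ammonium-fed 180 min against control 0.530 with the replicate block and 0.542 with the scan batch as a block, and in scan batch 1 alone 0.282 for endodermis markers in ammonium-fed 15 min against control and -0.0503 for touch and stress, -0.0410 for jasmonate and 0.118 for dividing cell markers in nitrate-fed 15 min against control. Signal over background limits the genes given as lower bounds, such as ORA47, CBF4, SRO4 and RABA4D, and the size of those given with a group partly at background, such as NRT2.5, RRTF1, JAZ8 and UPM1. The lower bounds hold for the main values only. With normexp and the 75th percentile the changes of CBF4 and RABA4D in ammonium-fed roots at 15 min fell short of them. So did that of NRT2.5 in nitrate-fed roots at 180 min against control. With normexp and the 75th percentile the calls of RABA4D and CBF4 in ammonium-fed roots at 15 min (adjusted p = 0.116 and 0.822) and of NRT2.5 in nitrate-fed roots at 180 min against control (adjusted p = 0.897) were lost.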

Other observations

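Some gene lists passed camera in the 15 min N-supplied controls (replicates 2 and 3 only) with the preset correlation but not with an estimated one. Iron deficiency genes had a median of 0.89 in the ammonium-fed control against 0 min (adjusted p = 0.19 with an estimated correlation) and of 0.562 in the nitrate-fed control (0.402). Energy and sugar starvation genes had a median of 0.72 in the nitrate-fed control (0.402). Shoot photosynthesis markers had medians of -1.66 (0.349) and -0.888 (0.542). No member of these lists was called in either control (0 of 26, 0 of 11 and 0 of 15).

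The N-supplied controls at 180 min were compared with 0 min only within replicate 3, with 1 array each and no test. The touch and stress list had a median of 1.56 in the ammonium-fed control and of 0.87 in the nitrate-fed control, both at percentile 100 of random lists of the same size matched on expression. Nitrogen starvation and scavenging genes had medians of -0.39 (percentile 0) and -0.19 (percentile 0.29). Clock genes had medians of -0.20 and -0.16, from members that went both ways (8 of 17 higher in each). These percentiles describe these arrays only and are no test, since random lists lack the correlation between list members.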
